A study of Homo sapiens with 9 samples.

How the data were processed

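Expression was measured on 9 single-colour Affymetrix arrays, 3 each for parental MCF7 cells and the tamoxifen-resistant lines TR1 and TR2. Per the labels' protocols, cells were grown in DMEM with serum and antibiotics, total RNA was extracted with a column kit, labelled with biotin and hybridised by the array maker's standard procedure. The same protocols list 4-hydroxytamoxifen at 0 uM, 1 uM and 100 nM without saying which line received which concentration. The deposited values, 1 per probe set and array, were taken as log2 expression: the scale is not stated, and the highest value lies under the ceiling of a 16-bit scanner on a log2 scale. The software, the background correction and the normalization between arrays are not given in the sources used here. Array means lay between 3.027 and 3.038 and array medians between 2.14 and 2.24, so the deposited log2 values had been brought to a common level by the authors or their software. A normalization of that kind sets the average change to near 0, so shares of genes higher and lower are relative to it. No 2 arrays held identical values, and 0 columns of sample values were left unmapped.

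Probe sets were named from the platform's annotation table, in which 41091 of 54675 had a single gene symbol, 1801 had several and 11721 were not listed with one. A further 62 were control probe sets. Probe sets with several symbols were not used, and the probe set with the highest mean over the 9 arrays represented each gene, giving 19775 genes, of which 19738 had a symbol in the RefSeq gene table. No filter on dim genes was applied. The background level of 3.58 is the 95th percentile of the array values of 36 leukocyte and endothelial marker genes, a level set after the values had been seen, and 9775 genes averaged above it. Between 66.6% and 67.9% of the values of an array lay under it. A fold against a line whose mean lies under that level was computed with the line raised to it, and is given as a lower bound.

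Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 9 arrays in 1 fit with group means), with Benjamini-Hochberg adjusted p under 0.05 over all genes, and an F test over the 3 lines. All p-values are two-sided. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 87 tests of 29 lists in 3 comparisons. Camera compares a list with the other genes. It was run again with the correlation estimated from the data. Limma's fry tests whether the genes of a list move, on balance, in one direction, without comparing them with other genes, and passed 19, 16 and 14 lists in TR1 against parental, TR2 against parental and TR2 against TR1. Of 30 lists fixed, the list of mitochondrially encoded transcripts had fewer than 5 measured members and was not tested. The groups, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined.

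The rule named, per comparison, the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold whose 3 arrays in one line all lay on one side of the 3 of the other and whose mean in the higher line exceeded the median gene. It also named up to 4 members with the largest change of each list that passed or was discussed, and 18 genes whatever their values. Genes outside that rule are said to be named after their values were seen. Where comparisons shared the parental arrays, 100 simulations of unchanged groups gave the overlap, correlation and covariance with no gene changed.

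Alternatives were quantile normalization, subtraction of array medians, leaving out the lowest 25% of genes or those under the median of gene means, the mean or the most variable of a gene's probe sets, an intensity trend or robust prior in eBayes, the replicate number as a block, fits with only the lines compared, leaving out each array in turn, adjusted p under 0.01, limma's treat against a log2 change of 0.5, and the other list tests. Numbers of settings and ranges of adjusted p in the text are over those that keep the test of a call, so without fry, treat and the lower threshold. With 1 array left out, a line kept 2 arrays and the spread was pooled over lines. Chosen after seeing the data were the hybridisation control level as a block, leaving out both arrays with high controls, the beta-actin 3' minus 5' signal (1.33 to 2.49 over the arrays) as a covariate, and raising values to the background level.

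The limma step was tested on simulated data for TR1 against parental with 19775 genes and independent noise. In these data 67 genes were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. The step recovered 56.7% of those changed by 0.5, 98.5% of those changed by 1 and 100% of those changed by 2. Of 179 calls, 9 were false (5.03%). The real comparison called 4816 genes, a far larger share, so these rates need not hold there. Neighbouring genes were scanned in windows of 25 among 9763 genes above background, ordered as in the RefSeq table of assembly GRCh38.p14, against 200 shuffled orders. On simulated data a block shifted by 1 was found in 100% of 60 trials in every comparison. A shift of 0.5 was found in 33.3% for TR1, 35% for TR2 and 100% for TR2 against TR1, so smaller blocks against parental would mostly be missed. With no shift, a window passed in 1.67%, 6.67% and 5% of trials. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.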

Results

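The samples were cultures of MCF7, an oestrogen receptor positive luminal breast cancer line, and of 2 lines derived from it that had acquired resistance to tamoxifen, MCF7-TR1 and MCF7-TR2, here TR1 and TR2. Tamoxifen is a drug that binds the oestrogen receptor and blocks its activity in breast cells, and 4-hydroxytamoxifen is its active metabolite. Total RNA of each line was hybridised to 3 arrays, 9 in all, each carrying 54675 probe sets. The culture description lists 4-hydroxytamoxifen at 0 and 1 uM and at 100 nM without tying a concentration to a line, so drug exposure and acquired change are not separable here. The scale of the values is not stated, and they were read as log2, with a median gene level of 3.52. The number of arrays limits the precision, and nothing in the sample descriptions says that the 3 arrays of a line came from separate cultures, so p-values measure the spread between these samples, which may be technical.

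The lines separated clearly. Arrays of the same line correlated at 0.992 to 0.9974 across genes, arrays of TR1 and parental at 0.9719 to 0.9773, arrays of TR2 and parental at 0.9706 to 0.9782, and arrays of the resistant lines with each other at 0.9892 to 0.9914. Genes are not independent replicates in these correlations. The first principal component held 68% of the variance and set the parental arrays (39.9 to 45.9) apart from the 6 resistant arrays, and the second, with 16.7%, set TR1 apart from TR2. The third component, with 7.5%, set parental replicate 1 (20.1) apart from parental replicates 2 (-10.6) and 3 (-12.3), and TR1 replicate 2 (10.6) apart from TR1 replicates 1 (-7.7) and 3 (-4.07). Hybridisation controls, added to each sample before the array step, averaged 9.63 in parental replicate 2 and 9.36 in TR2 replicate 1, against 7.76 to 8.04 in the other arrays.

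**Figure D1:**
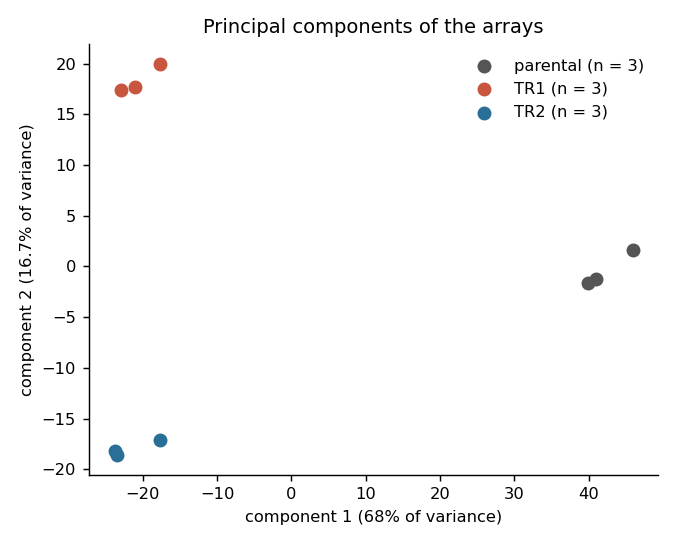
Each point is 1 array, placed by its score on component 1 (68% of the variance) and component 2 (16.7%), coloured by line, with 3 arrays per line. The parental arrays lie between 39.9 and 45.9 on component 1 and the TR1 and TR2 arrays lie on opposite sides of 0 on component 2.

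Across the 3 lines, 5783 of 19775 genes differed by the limma F test. In TR1 against parental, 4816 genes changed, of which 2785 rose and 2031 fell. In TR2 against parental, 5026 changed, 2784 up and 2242 down, and between TR2 and TR1, 1793 differed, 841 higher and 952 lower in TR2. With array medians subtracted, the share of changed genes that rose went from 57.8% to 70.8% in TR1 and from 55.4% to 65.8% in TR2, while with quantile normalization it was 48.3% in TR1 (2438 up, 2614 down) and 45.7% in TR2 (2435 up, 2890 down). The balance of rises and falls among all calls therefore depended on the scaling. Among calls changed by at least 2-fold, rises outnumbered falls under each of these scalings. In TR1 they were 792 and 238 as deposited, 659 and 298 with quantile normalization and 908 and 201 with array medians subtracted. In TR2 they were 818 and 260, 697 and 321, and 910 and 230. With the hybridisation control level as a block the counts were 4281, 5284 and 1668, and among the 7 arrays of low control level they were 4080, 4233 and 1383, while the high-level batch held 1 parental and 1 TR2 array and gave no fit of its own. With values under the background level raised to it, 3235 genes changed in TR1, 3311 changed in TR2 and 1215 differed between TR2 and TR1. Without TR2 replicate 2, 1074 genes differed between TR2 and TR1, and without TR1 replicate 3, 1130 did. Counts of falls moved more than totals, from 2031 to 1334 in TR1 without TR1 replicate 3 and from 2242 to 1451 in TR2 without TR2 replicate 2.

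The first comparison set TR1 against the parental line. Genes that the oestrogen receptor switches on were lower in TR1. GREB1, a growth regulator induced by oestrogen, averaged 8.29 ± 0.19 (SD, n = 3) in parental cells and 0.68 ± 0.09 in TR1, a fall of at least 26.2-fold. The progesterone receptor gene PGR fell from 7.28 ± 0.15 to 2.92 ± 0.19, at least 13-fold, and the scaffold gene PDZK1 from 7.56 ± 0.03 to 3.21 ± 0.25, at least 15.7-fold. Throughout, where the lower line lay under the background level of 3.58, a fold is given as "at least", computed with that line raised to the background level. Folds and such bounds hold for the probe set that represents the gene, and other probe sets can give smaller ones. With the mean of a gene's probe sets, 438 genes rose and 173 fell by at least 2-fold in TR1, against 792 and 238. The secreted trefoil factor TFF1 fell by 2.15 on the log2 scale and remained at 10.53 ± 0.13, while ESR1, which encodes the receptor, fell by 0.67 (SE 0.12, adjusted p = 0.0011), a call lost when the values of its probe sets were averaged (-0.18, adjusted p = 0.099; adjusted p from 0.00029 to 0.099 over 23 settings).

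Of 37 measured oestrogen receptor targets, 28 fell, 6 rose and 3 did not pass, and the same counts held adjusted over the list alone. Besides GREB1, PGR and PDZK1, the chemokine gene CXCL12 fell at least 12.9-fold, the fatty acid elongase ELOVL2 at least 12.9-fold, and the carbonic anhydrase gene CA12 fell by 4.46 (22-fold). The median log2 fold change of the list was -0.88, and limma's camera test gave adjusted p = 4.5e-13, or adjusted p = 0.021 with an estimated correlation. Those that rose included STC2 (1.47) and MYC (1.09).

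**Figure D2:**
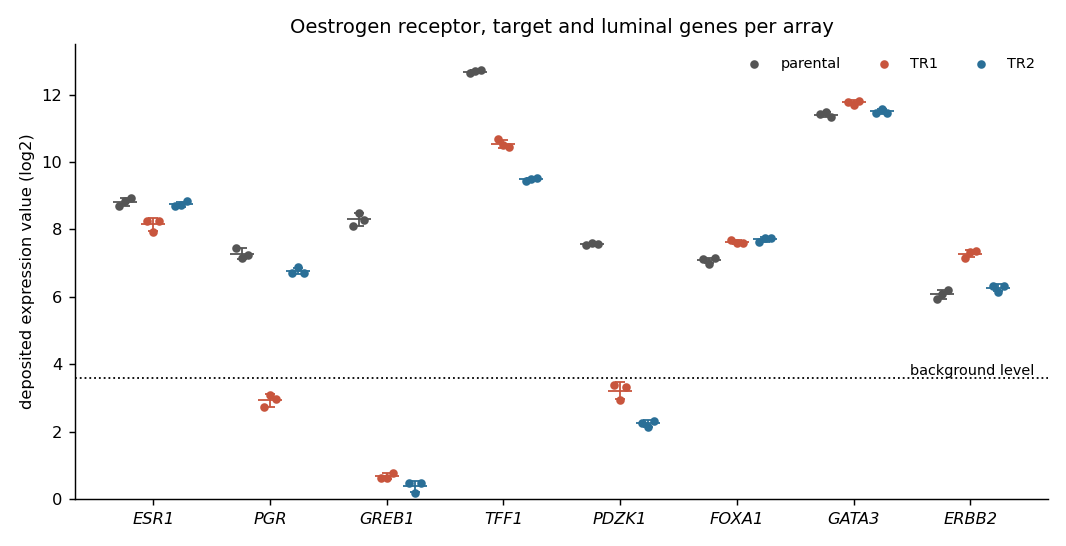
Deposited log2 expression of 8 genes in each array, with points for arrays, dashes for the line mean and bars for the SD (n = 3), and a dotted line at the background level of 3.58. GREB1 and PDZK1 lie above background in the parental arrays and below it in both resistant lines, while PGR does so in TR1 and averages 6.77 in TR2.

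The 6 largest fitted rises in TR1 were of genes that lay under background in the parental arrays, where fitted values give no order of size. IGFBP5, which binds insulin-like growth factors, rose from 1.41 ± 0.19 to 9.36 ± 0.08, at least 54.8-fold (adjusted p = 9.4e-12). The ligand TGFB2 rose at least 26.5-fold, the neuronal membrane protein gene SLITRK6 at least 7.85-fold, the glucose-1,6-bisphosphate synthase PGM2L1 at least 6.17-fold, the actin-binding caldesmon gene CALD1 at least 5.1-fold and the ephrin receptor gene EPHA4 at least 4.84-fold. The 6 largest fitted falls were those of GREB1 and ELOVL2 and of S100A8, from 9.85 ± 0.12 to 1.57 ± 0.21 (at least 76.7-fold), its partner in calprotectin S100A9 (at least 22-fold), ARHGAP36 (at least 16.4-fold) and the protease inhibitor SERPINA3, which fell by 4.95 (31-fold, adjusted p = 1.3e-08).

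Genes induced by type I interferon fell together. Of 42 measured, 32 fell, none rose and 10 did not pass, with 34 lower adjusted over the list alone, and the median was -0.92 (camera adjusted p = 3e-19, and adjusted p = 0.0079 with an estimated correlation). IFIT1 fell at least 8.25-fold, IFI6 by 4.03 (16.3-fold), IFIT3 at least 4.98-fold and OAS1 at least 4.63-fold, with IFI6 at 8.66 ± 0.26 in parental cells and 4.63 ± 0.29 in TR1. Of the 42 genes 24 averaged above background, and with values raised to the background level the median shrank to -0.41 (adjusted p = 1.1e-14).

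Cell cycle genes were lower too. Of 38 genes of mitosis and G2/M, 34 fell and 0 rose (37 and 0 adjusted over the list alone), among them CDC20, which activates the anaphase-promoting complex (-1.51), HMMR (-1.31), the mitotic kinase gene AURKA (-1.17) and PTTG1 (-1.03). The median was -0.73, with camera adjusted p = 2.1e-17 and adjusted p = 0.056 with an estimated correlation. Of 37 genes of DNA replication and G1/S, 28 fell and 1 rose (29 and 2 adjusted over the list alone), including CDC6 (-1.31), MCM10 (-1.19), RRM2 (-1.08) and ORC1 (-1.05). This call, at adjusted p = 3.1e-11, had adjusted p = 0.12 with an estimated correlation. Of 33 replication-dependent histone genes, 17 fell and 1 rose (20 and 1 adjusted over the list alone), with H2BC9 at -1.99 and H4C11 at -1.83, and adjusted p = 3.2e-07, or adjusted p = 0.026 with an estimated correlation. Of these histone genes 8 averaged above background, and the median was 0 with values raised to the background level.

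Immediate early genes, which growth signals induce within minutes, rose in TR1. Of 28 measured, 17 rose and 3 fell (17 and 4 adjusted over the list alone), with a median of 0.93 and adjusted p = 6.1e-07, but adjusted p = 0.073 with an estimated correlation. EGR1 rose by 2.67 (6.35-fold), DUSP1 by 2.07 (4.19-fold), FOS at least 2.63-fold and CCN2 at least 2.23-fold, while the 3 that fell, named after their values were seen, were EGR3 (-1.96), DUSP5 (at least 2.49-fold) and FOSL1, which lay under background in both lines. Of 32 genes associated with stem and progenitor cells, 15 rose and 4 fell (17 and 6 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). SOX2, a pluripotency factor, rose by 3.85 (14.4-fold), DKK1, a secreted Wnt antagonist, by 2.9 (7.45-fold) and PROM1, which encodes CD133, at least 2.64-fold, while HEY2 fell at least 8.22-fold.

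Epithelial junction genes were higher, with 8 of 22 up and 1 down, the same adjusted over the list alone (adjusted p = 0.0024, and adjusted p = 0.082 with an estimated correlation), led by CLDN1, a tight junction protein gene that rose by 2.91 (7.53-fold), and by CGN (0.98) and CLDN4 (0.93). Without the lower part of genes by mean level the junction call had adjusted p = 0.11, the highest of 24 settings, the lowest being 0.0019. Another CLDN4 probe set was called in the opposite direction. Of 23 luminal identity genes, 13 rose and 5 fell, the same adjusted over the list alone (median 0.36, adjusted p = 0.036, and adjusted p = 0.13 with an estimated correlation). The luminal call was lost without parental replicate 3 (adjusted p = 0.051) and without TR1 replicate 3 (adjusted p = 0.051), and in all under 6 of 24 settings, with adjusted p from 0.023 to 0.41. Members included ERBB3 (1.35), TBX3 (1.3), BCL2 (-1.73) and the prolactin receptor gene PRLR (-1.26).

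Among genes named in advance whatever their values, ERBB2, the HER2 receptor gene, rose by 1.21 (2.32-fold, adjusted p = 5.7e-06), MYC by 1.09 (adjusted p = 0.0032), the intermediate filament gene VIM by 1.02 from 3.75 ± 0.18, and the pioneer factor gene FOXA1 by 0.54. GATA3 rose by 0.36 (adjusted p = 0.012, and adjusted p = 0.052 without TR1 replicate 3). The efflux transporter gene ABCG2 fell by 0.76. CCND1, which encodes cyclin D1, fell by 0.42 (adjusted p = 0.013), a call lost without TR1 replicate 1 (adjusted p = 0.05), without TR1 replicate 3 (adjusted p = 0.063) and with the mean of its probe sets (adjusted p = 0.14; 0.0037 to 0.35 over 23 settings). CYP1A1, under background in parental cells at 3.3, passed with a difference of at least 1.27-fold (adjusted p = 0.014), a call lost with values raised to the background level (0.34, adjusted p = 0.19), without parental replicate 2 (adjusted p = 0.052) and without TR1 replicate 3 (adjusted p = 0.062; 0.0051 to 0.19 over 23 settings). KRT8 differed by 0.53 (adjusted p = 0.044), and its call was lost without parental replicate 2 (adjusted p = 0.16), parental replicate 3 (0.15), TR1 replicate 1 (0.089), TR1 replicate 2 (0.11), TR1 replicate 3 (0.11), TR2 replicate 1 (0.055) or TR2 replicate 2 (0.052), 12 of 23 settings ending it in all. CDKN1A (-0.14, adjusted p = 0.43), ABCB1 (-0.04, adjusted p = 0.77) and CDH1 (-0.01, adjusted p = 0.96) did not pass, nor did EGFR (0.3, adjusted p = 0.24), which lay under background, as ABCB1 did, and passed without parental replicate 1 (0.52, adjusted p = 0.0098). Another EGFR probe set was called in the opposite direction.

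In TR1, 9 of the 29 lists tested passed, 4 higher and 5 lower, and 3 passed with an estimated correlation, the oestrogen receptor target, interferon and histone lists. Those not passed are given with their members past the threshold. Basal and myoepithelial markers had 7 of 17 members higher and 0 lower, and 7 and 0 adjusted over the list alone (adjusted p = 0.057). Mesenchymal side of the epithelial-mesenchymal transition had 4 of 24 members higher and 2 lower, and 4 and 2 adjusted over the list alone (adjusted p = 0.96, median -0.091, mean 0.23, test direction up). Receptor tyrosine kinases and their ligands had 7 of 30 members higher and 4 lower, and 7 and 4 adjusted over the list alone (adjusted p = 0.75, median -0.056, mean 0.12, test direction up). Antigen presentation by MHC class I had 5 of 17 members higher and 3 lower, and 5 and 3 adjusted over the list alone (adjusted p = 0.86, median -0.031, mean -7e-04, test direction up). Inflammatory cytokines and NF-kB targets had 5 of 26 members higher and 4 lower, and 5 and 4 adjusted over the list alone (adjusted p = 0.86, median -0.051, mean 0.051, test direction up). Cholesterol synthesis and uptake had 8 of 20 members higher and 1 lower, and 8 and 1 adjusted over the list alone (adjusted p = 0.083). Fatty acid synthesis and handling had 4 of 21 members higher and 3 lower, and 6 and 4 adjusted over the list alone (adjusted p = 0.56, median -0.012, mean 0.11, test direction up). Unfolded protein response had 4 of 21 members higher and 6 lower, and 4 and 6 adjusted over the list alone (adjusted p = 0.86). ATF4 and amino acid stress targets had 4 of 30 members higher and 9 lower, and 4 and 11 adjusted over the list alone (adjusted p = 0.13). Hypoxia and glycolysis had 7 of 32 members higher and 6 lower, and 9 and 8 adjusted over the list alone (adjusted p = 0.87, median -0.14, mean 0.072, test direction down).

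Oxidative stress response had 8 of 24 members higher and 4 lower, and 10 and 7 adjusted over the list alone (adjusted p = 0.29). Drug metabolism and efflux had 8 of 29 members higher and 5 lower, and 8 and 10 adjusted over the list alone (adjusted p = 0.95, median -0.13, mean 0.14, test direction up). P53 targets had 3 of 27 members higher and 11 lower, and 5 and 12 adjusted over the list alone (adjusted p = 0.067). Apoptosis regulators of the BCL2 family and caspases had 9 of 26 members higher and 3 lower, and 10 and 4 adjusted over the list alone (adjusted p = 0.18). Chromatin regulators tied to endocrine therapy response had 6 of 25 members higher and 2 lower, and 6 and 2 adjusted over the list alone (adjusted p = 0.057). Cytosolic ribosomal proteins had 0 of 35 members higher and 0 lower, and 0 and 0 adjusted over the list alone (adjusted p = 0.89, median 0.0041, mean -0.00075, test direction up). Fibroblast markers had 2 of 20 members higher and 0 lower, and 2 and 0 adjusted over the list alone (adjusted p = 0.93, median -0.11, mean 0.078, test direction down). Leukocyte markers had 0 of 18 members higher and 3 lower, and 0 and 1 adjusted over the list alone (adjusted p = 0.057). Endothelial markers had 2 of 18 members higher and 0 lower, and 2 and 0 adjusted over the list alone (adjusted p = 0.86). Basal-like and claudin-low breast cancer line markers had 5 of 24 members higher and 4 lower, and 5 and 4 adjusted over the list alone (adjusted p = 0.62).

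The second comparison set TR2 against the parental line. Oestrogen receptor targets were lower in TR2 too, while PGR stood at 69.9% of its parental level. GREB1 fell from 8.29 ± 0.19 (SD, n = 3) to 0.38 ± 0.17, at least 26.2-fold, PDZK1 to 2.24 ± 0.09, at least 15.7-fold, and TFF1 by 3.2 (9.2-fold) to 9.48 ± 0.04. PGR fell by 0.52 (SE 0.12, adjusted p = 0.008) to 6.77 ± 0.1. ESR1 averaged 8.74 ± 0.08 against 8.81 ± 0.12 in parental cells (-0.07, adjusted p = 0.68).

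Of 37 oestrogen receptor targets, 26 fell and 3 rose, the same adjusted over the list alone, with a median of -0.76 (camera adjusted p = 1.6e-10, and adjusted p = 0.026 with an estimated correlation). CXCL12 fell at least 12.9-fold and EGR3 at least 15.7-fold, and the 3 that rose, named after their values were seen, were KRT13 (at least 1.9-fold), STC2 (2.2) and NHERF1 (0.64). Interferon-response genes fell, with 31 of 42 lower and 0 higher (32 and 1 adjusted over the list alone), a median of -0.94 and adjusted p = 2.2e-17, or adjusted p = 0.0079 with an estimated correlation. With values raised to the background level the median shrank to -0.46 (adjusted p = 2.5e-14). IFI6 fell by 3.96 (15.5-fold), IFIT1 at least 8.25-fold, OAS1 at least 4.63-fold and IFI27 at least 3.15-fold.

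The 6 largest fitted rises in TR2, also of genes under background in parental cells and so without order of size, were of FGFBP2, from 1.43 ± 0.39 to 7.51 ± 0.21 (at least 15.2-fold), the synaptic organiser gene CBLN2 (at least 14.1-fold), SLITRK6 (at least 13.6-fold), the carbonic anhydrase gene CA2 (at least 9.54-fold), IGFBP5 (at least 8-fold) and EPHA4 (at least 6.82-fold). The 6 largest fitted falls were those of GREB1 and PDZK1 and of S100A8, to 1.24 ± 0.28 (at least 76.7-fold), SERPINA3 (at least 40.9-fold), S100A9 (at least 22-fold) and ARHGAP36 (at least 16.4-fold).

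Amino acid stress genes driven by ATF4 and genes of fatty acid synthesis were higher in TR2. Of 30 ATF4 targets, 13 rose and 2 fell (15 and 4 adjusted over the list alone, adjusted p = 0.00064, and adjusted p = 0.13 with an estimated correlation). DDIT4, an inhibitor of mTORC1, rose by 3.32 (9.97-fold), STC2 by 2.2 (4.6-fold), PHGDH, the first enzyme of serine synthesis, by 1.48 (2.79-fold) and NUPR1 by 1.34 (2.53-fold). Of 21 fatty acid genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.0032, and adjusted p = 0.13 with an estimated correlation), with the lipogenic regulator SREBF1 up by 2.09 (4.27-fold), FASN by 1.76 (3.39-fold) and the desaturase SCD by 1.42 (2.67-fold). With the most variable probe set of each gene, the fatty acid call had adjusted p = 0.088, within a range of 0.0027 to 0.13 over 24 settings, and without the lower part of genes by mean level the fatty acid (0.075), cholesterol (0.065) and ATF4 (0.052) calls all ended. Of 20 cholesterol genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.0021, and adjusted p = 0.094 with an estimated correlation), among them LSS (1.33), STARD4 (1.08), LPIN1 (0.89) and INSIG1 (0.8).

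Cell cycle genes fell. Of 38 genes of mitosis and G2/M, 24 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -0.49 and adjusted p = 1.5e-08, or adjusted p = 0.13 with an estimated correlation, and CDC20 (-1.38), AURKA (-1.18), UBE2C (-0.98) and CCNB1 (-0.89) among them. Of 37 genes of DNA replication and G1/S, 17 fell and 1 rose (17 and 2 adjusted over the list alone, adjusted p = 0.00012, and adjusted p = 0.29 with an estimated correlation), including CDC6 (-1.01), MCM10 (-0.98) and ORC6 (-0.97). Of 33 histone genes, 12 fell and 2 rose (12 and 3 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.13 with an estimated correlation), including H2BC9 (-1.59) and H4C11 (-1.37). The histone call ended with values raised to the background level (median 0, adjusted p = 0.15) and without the lowest 25% of genes (0.062), within 0.0054 to 0.15 over 24 settings.

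Of 28 immediate early genes, 13 rose and 5 fell (13 and 7 adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.27 with an estimated correlation), with CCN2 up at least 2.44-fold and DUSP5 down at least 2.49-fold. The immediate early call ended with values raised to the background level (adjusted p = 0.06), and had adjusted p from 0.0098 to 0.27 over 24 settings. Of 17 basal and myoepithelial markers, 8 rose and 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.13 with an estimated correlation), with CAV1 up at least 3.33-fold, CAV2 at least 3.71-fold and ITGA6 by 1.61, and the call was lost without parental replicate 1 (adjusted p = 0.051) and under 5 of 24 settings in all. Of 27 p53 targets, 9 fell and 3 rose (12 and 3 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.41 with an estimated correlation), with GADD45A at -1.22 and TIGAR at -1.13 against TP53INP1 at 1.39 and ZMAT3 at 1.27. That call was lost without parental replicate 1 (adjusted p = 0.051) and without TR2 replicate 1 (adjusted p = 0.082), with adjusted p from 0.00055 to 0.41 over 24 settings. Of 25 chromatin regulators, 6 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.046, and adjusted p = 0.27 with an estimated correlation), including NCOA1 (1.37), TBX3 (1.17) and NCOA2 (1.08), a call lost without parental replicate 1 (adjusted p = 0.065), parental replicate 3 (0.06) or TR2 replicate 3 (0.09), and under 11 of 24 settings in all.

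Markers of other cell types were measured beside these groups. Of 18 leukocyte markers, 0 rose and 2 fell, the same adjusted over the list alone (median -0.22, adjusted p = 0.044, and adjusted p = 0.5 with an estimated correlation). The background level was set from these and endothelial markers, so by construction they lie mostly under it. CORO1A averaged 3.4 ± 0.48 in parental cells and 2.59 ± 0.16 in TR2, and LYZ 1.74 ± 0.17 and 1.14 ± 0.05. The leukocyte call was lost without parental replicate 1 (adjusted p = 0.11), parental replicate 2 (0.056), TR2 replicate 2 (0.07) or TR2 replicate 3 (0.099), with quantile normalization (0.23) and under 10 of 23 settings in all, with adjusted p from 0.013 to 0.86. The highest came with values raised to the background level, which flattens these markers by construction. Of the genes named in advance, FOXA1 rose by 0.62 and VIM by 1.42, and CCND1 fell by 0.6 (adjusted p = 0.0014, and adjusted p = 0.11 with the mean of its probe sets, within 0.00035 to 0.47 over 23 settings), CDKN1A by 0.6 and ABCG2 at least 2.08-fold. ERBB2 (0.2, adjusted p = 0.2), GATA3 (0.09, adjusted p = 0.52), EGFR (0.13, adjusted p = 0.63), ABCB1 (-0.01, adjusted p = 0.96), CYP1A1 (0.31, adjusted p = 0.18), KRT8 (-0.34, adjusted p = 0.18) and CDH1 (-0.16, adjusted p = 0.21) did not pass, with EGFR and ABCB1 under background in both lines and CYP1A1 in the parental line. MYC did not pass (0.42, adjusted p = 0.19) and passed without parental replicate 1 (0.69, adjusted p = 0.014). KRT8 passed with the beta-actin end signal as a covariate (-0.46, adjusted p = 0.0064).

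In TR2, 13 of the 29 lists passed, 6 higher and 7 lower, and 2 passed with an estimated correlation, the oestrogen receptor target and interferon lists. Luminal epithelial identity had 9 of 23 members higher and 6 lower, and 9 and 6 adjusted over the list alone (adjusted p = 0.48, median -0.032, mean 0.019, test direction up). Mesenchymal side of the epithelial-mesenchymal transition had 5 of 24 members higher and 2 lower, and 5 and 2 adjusted over the list alone (adjusted p = 0.86, median -0.079, mean 0.13, test direction up). Epithelial junctions had 6 of 22 members higher and 3 lower, and 6 and 3 adjusted over the list alone (adjusted p = 0.56). Receptor tyrosine kinases and their ligands had 5 of 30 members higher and 6 lower, and 5 and 6 adjusted over the list alone (adjusted p = 0.89, median -0.013, mean 0.081, test direction up). Antigen presentation by MHC class I had 3 of 17 members higher and 4 lower, and 3 and 4 adjusted over the list alone (adjusted p = 0.86, median -0.008, mean 0.028, test direction up). Inflammatory cytokines and NF-kB targets had 2 of 26 members higher and 2 lower, and 2 and 2 adjusted over the list alone (adjusted p = 0.57). Unfolded protein response had 4 of 21 members higher and 6 lower, and 4 and 9 adjusted over the list alone (adjusted p = 0.54). Hypoxia and glycolysis had 7 of 32 members higher and 13 lower, and 8 and 16 adjusted over the list alone (adjusted p = 0.26).

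Oxidative stress response had 5 of 24 members higher and 5 lower, and 6 and 6 adjusted over the list alone (adjusted p = 0.86, median -0.059, mean 0.036, test direction up). Drug metabolism and efflux had 8 of 29 members higher and 6 lower, and 8 and 8 adjusted over the list alone (adjusted p = 0.86, median -0.085, mean 0.13, test direction up). Apoptosis regulators of the BCL2 family and caspases had 5 of 26 members higher and 6 lower, and 5 and 6 adjusted over the list alone (adjusted p = 0.85, median -0.047, mean 0.089, test direction up). Stem and progenitor associated genes had 10 of 32 members higher and 6 lower, and 10 and 7 adjusted over the list alone (adjusted p = 0.35, median -0.054, mean 0.34, test direction up). Cytosolic ribosomal proteins had 1 of 35 members higher and 1 lower, and 0 and 0 adjusted over the list alone (adjusted p = 0.62). Fibroblast markers had 2 of 20 members higher and 1 lower, and 2 and 1 adjusted over the list alone (adjusted p = 0.98, median -0.098, mean 0.13, test direction up). Endothelial markers had 1 of 18 members higher and 0 lower, and 0 and 0 adjusted over the list alone (adjusted p = 0.87). Basal-like and claudin-low breast cancer line markers had 8 of 24 members higher and 5 lower, and 8 and 5 adjusted over the list alone (adjusted p = 0.5).

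**Figure D3:**
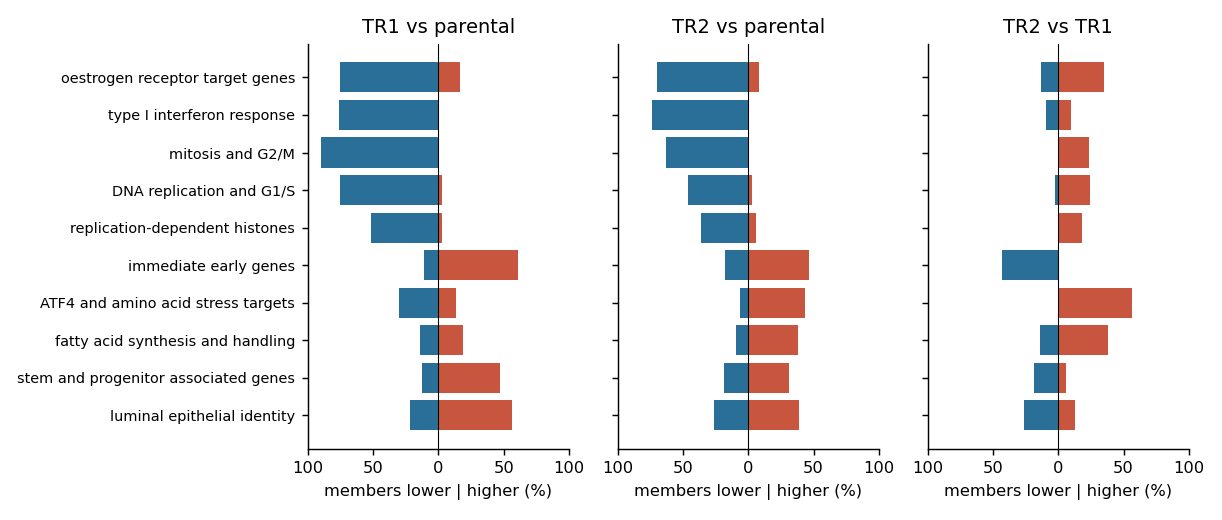
Share of the measured members of 10 gene lists that passed the test as higher (right, red) or lower (left, blue), for each comparison. Interferon-response genes had 32 of 42 members lower in TR1 and 31 in TR2, and ATF4 targets had 17 of 30 higher in TR2 than in TR1.

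Changes in the resistant lines were largely shared. In the same direction in both, 3232 genes changed, 1954 up and 1278 down, while 56 changed in opposite directions. The split depended on the scaling, with 1669 up and 1793 down after quantile normalization and 2276 up and 890 down with array medians subtracted. Unchanged groups simulated against the same parental arrays gave an overlap of 0. That was near certain in advance, since groups without changed genes give almost no calls, so it does not show what the shared arrays add. Independent lists of these sizes would share 392 genes up and 230 down, a figure that leaves the shared arrays out. Fold changes of the lines correlated at 0.832 across genes (Spearman 0.758), against 0.501 simulated for unchanged groups that share the parental arrays, and the covariance was 0.24 against a simulated 0.00891, a difference of 0.231. With 3 parental arrays no split left 2 in each part, so part of the excess overlap can come from the shared arrays. Of the genes changed the same way, 556 also differed between TR2 and TR1.

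**Figure D4:**
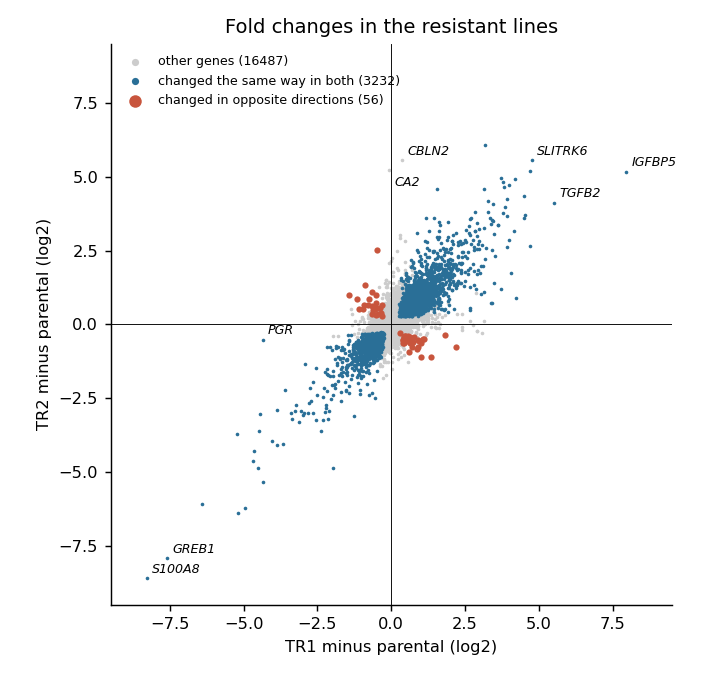
Each point is a gene, placed by its log2 difference from parental in TR1 (horizontal) and TR2 (vertical). Blue points are the 3232 genes that changed the same way in both lines and red points the 56 that changed in opposite directions.

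The third comparison set TR2 against TR1. The oestrogen receptor target PGR differed, at 6.77 ± 0.1 (SD, n = 3) in TR2 and 2.92 ± 0.19 in TR1, at least 9.08-fold (adjusted p = 8.8e-09). CA2 was higher in TR2 by at least 9.54-fold, CBLN2 by at least 14.1-fold, the epithelial sodium channel gene SCNN1A by 3.04 (8.25-fold), FGFBP2 by 2.92 (7.57-fold) and the chloride channel gene CLIC3 by at least 2.93-fold. Lower in TR2 were SH3BGRL (-3.34, 10.1-fold), CLDN1 (at least 7.68-fold), GPNMB (-2.97, 7.85-fold), EGR3 (at least 4.02-fold), CSGALNACT1 (at least 3.85-fold) and CDKN2B, which encodes the cell cycle inhibitor p15 (at least 2.56-fold).

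ATF4 targets stood out. Of 30, 17 were higher in TR2 and 0 lower (19 and 0 adjusted over the list alone), with a median difference of 0.46 and adjusted p = 5.8e-17, or adjusted p = 0.021 with an estimated correlation. NUPR1 was higher by at least 2.62-fold, and the amino acid synthesis genes PSAT1 by 1.5 (2.83-fold), ASNS by 1.12 (2.17-fold) and PHGDH by 1.07 (2.11-fold). Of 21 fatty acid genes, 8 were higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.00012, and adjusted p = 0.082 with an estimated correlation), with SREBF1 at 2.16, FASN at 1.71 and SCD at 1.37. Some cell cycle genes were higher in TR2 than in TR1, though none of their lists passed with an estimated correlation. Of 38 genes of mitosis and G2/M, 9 were higher and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 7.4e-09, and adjusted p = 0.13 with an estimated correlation), including NDC80 (0.96). Of 37 genes of DNA replication and G1/S, 9 were higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 1.7e-06, and adjusted p = 0.22 with an estimated correlation), including TYMS (0.84) and POLE2 (0.61). Of 33 histone genes, 6 were higher and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 1e-04, and adjusted p = 0.056 with an estimated correlation), including H1-2 (1.24) and H2AC6 (1.16). Only 8 of the 33 averaged above background.

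Immediate early genes were lower in TR2 than in TR1, with 12 of 28 lower and 0 higher (14 and 0 adjusted over the list alone, adjusted p = 5.3e-08, and adjusted p = 0.056 with an estimated correlation), among them EGR1 (-2.11, 4.3-fold), NR4A2 (-1.29) and IER5 (-0.99). Of 22 junction genes, 6 were lower and 0 higher (7 and 1 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.082 with an estimated correlation), including CLDN1 and CLDN7 (-0.62). Of 32 stem and progenitor genes, 6 were lower and 2 higher (10 and 2 adjusted over the list alone, adjusted p = 0.0076, and adjusted p = 0.33 with an estimated correlation), including SOX4 (-1.49), HES1 (-1.12) and CD24 (-0.98), and without the lower part of genes by mean level it had adjusted p = 0.05. Of 32 hypoxia and glycolysis genes, 7 were lower and 0 higher (8 and 2 adjusted over the list alone, adjusted p = 0.041, and adjusted p = 0.5 with an estimated correlation), including KDM3A (-0.68). The hypoxia call was lost without TR1 replicate 1 (adjusted p = 0.16) or TR2 replicate 1 (adjusted p = 0.13) and with the hybridisation control level as a block (adjusted p = 0.063), and under 9 of 24 settings in all. Of 37 oestrogen receptor targets, 13 were higher and 5 lower (13 and 6 adjusted over the list alone, median 0.093, adjusted p = 0.033, and adjusted p = 0.27 with an estimated correlation), with RERG (1.58) higher and TFF1 (-1.05) lower. This call was lost without TR2 replicate 3 (adjusted p = 0.1), with adjusted p from 0.011 to 0.27 over 24 settings.

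Of the genes named in advance, TFF1 (-1.05, adjusted p = 4.1e-05), ERBB2 (-1.02, adjusted p = 1e-04), ABCG2 (at least 1.23-fold, adjusted p = 0.0014) and KRT8 (-0.87, adjusted p = 0.0079) were lower in TR2, and so was PDZK1 (adjusted p = 0.00042), with both lines under background. With values raised to the background level PDZK1 (0, adjusted p = 1) and ABCG2 (-0.3, adjusted p = 0.35) did not pass. KRT8 did not pass there either (adjusted p = 0.069), though it lay far above background and its difference stayed at -0.87. ESR1 was higher by 0.6 (adjusted p = 0.0067, and 0.09 with adjusted p = 0.63 for the mean of its probe sets). CDKN1A was lower by 0.46 (-0.46, adjusted p = 0.034), a call lost without TR1 replicate 1 (0.12), 2 (0.064) or 3 (0.11) and without TR2 replicate 1 (0.059), 2 (0.15) or 3 (0.06), values being adjusted p, and under 10 of 23 settings in all. GREB1 (-0.3, adjusted p = 0.19), FOXA1 (0.08, adjusted p = 0.76), GATA3 (-0.27, adjusted p = 0.096), EGFR (-0.17, adjusted p = 0.7), CCND1 (-0.18, adjusted p = 0.43), ABCB1 (0.03, adjusted p = 0.91), CYP1A1 (-0.31, adjusted p = 0.33) and CDH1 (-0.16, adjusted p = 0.42) did not pass, with GREB1, EGFR and ABCB1 under background in both lines. MYC (-0.66, adjusted p = 0.093) and VIM (0.4, adjusted p = 0.056) did not pass with all arrays. Without parental replicate 1 they did (MYC adjusted p = 0.02, VIM adjusted p = 0.04), as VIM did without parental replicate 2 (adjusted p = 0.037), and in all MYC passed under 3 settings and VIM under 6. GATA3 passed under 4 of 23 settings.

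Between TR2 and TR1, 10 of the 29 lists passed, 6 higher and 4 lower, and 1 passed with an estimated correlation, the ATF4 list. Luminal epithelial identity had 3 of 23 members higher and 6 lower, and 5 and 8 adjusted over the list alone (adjusted p = 0.2). Basal and myoepithelial markers had 2 of 17 members higher and 1 lower, and 2 and 2 adjusted over the list alone (adjusted p = 0.86, median -0.032, mean 0.034, test direction up). Mesenchymal side of the epithelial-mesenchymal transition had 1 of 24 members higher and 3 lower, and 2 and 3 adjusted over the list alone (adjusted p = 0.87, median 0.036, mean -0.1, test direction down). Receptor tyrosine kinases and their ligands had 2 of 30 members higher and 5 lower, and 2 and 5 adjusted over the list alone (adjusted p = 0.59). Type I interferon response had 4 of 42 members higher and 4 lower, and 6 and 4 adjusted over the list alone (adjusted p = 0.31). Antigen presentation by MHC class I had 0 of 17 members higher and 1 lower, and 2 and 1 adjusted over the list alone (adjusted p = 0.86, median -0.015, mean 0.028, test direction up). Inflammatory cytokines and NF-kB targets had 0 of 26 members higher and 4 lower, and 0 and 5 adjusted over the list alone (adjusted p = 0.067). Cholesterol synthesis and uptake had 4 of 20 members higher and 2 lower, and 4 and 2 adjusted over the list alone (adjusted p = 0.057). Unfolded protein response had 1 of 21 members higher and 0 lower, and 1 and 0 adjusted over the list alone (adjusted p = 0.54). Oxidative stress response had 1 of 24 members higher and 6 lower, and 2 and 6 adjusted over the list alone (adjusted p = 0.13).

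Drug metabolism and efflux had 1 of 29 members higher and 3 lower, and 1 and 3 adjusted over the list alone (adjusted p = 0.89, median 0.023, mean -0.0065, test direction up). P53 targets had 3 of 27 members higher and 6 lower, and 3 and 6 adjusted over the list alone (adjusted p = 0.8). Apoptosis regulators of the BCL2 family and caspases had 3 of 26 members higher and 5 lower, and 3 and 5 adjusted over the list alone (adjusted p = 0.2). Chromatin regulators tied to endocrine therapy response had 2 of 25 members higher and 1 lower, and 3 and 3 adjusted over the list alone (adjusted p = 0.89). Cytosolic ribosomal proteins had 0 of 35 members higher and 0 lower, and 0 and 0 adjusted over the list alone (adjusted p = 0.58). Fibroblast markers had 2 of 20 members higher and 2 lower, and 2 and 2 adjusted over the list alone (adjusted p = 0.87). Leukocyte markers had 0 of 18 members higher and 0 lower, and 0 and 0 adjusted over the list alone (adjusted p = 0.86). Endothelial markers had 0 of 18 members higher and 1 lower, and 0 and 1 adjusted over the list alone (adjusted p = 0.96, median -0.0036, mean -0.0053, test direction up). Basal-like and claudin-low breast cancer line markers had 2 of 24 members higher and 1 lower, and 3 and 1 adjusted over the list alone (adjusted p = 0.86, median -0.025, mean 0.0065, test direction up).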

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

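The tests of PGR below were chosen after the result was seen, as was the hybridisation control block and the beta-actin covariate used for the interferon genes. Between the resistant lines, 1793 genes differed by limma's direct test and 56 changed in opposite directions against parental. Splitting the 6 arrays of 2 lines otherwise gave few alternatives. In each comparison 1 of the 10 splits, the real one, gave as many genes or lists, and 10 splits are too few for a share under 0.05. The real and highest other counts of genes were 4816 and 0 for TR1 against parental, 5026 and 0 for TR2 against parental, and 1793 and 0 for TR2 against TR1. Those of lists were 9 and 8, 13 and 6, and 10 and 6. Splits that mixed the lines and gave 0 genes thus still gave up to 8, 6 and 6 lists. Camera at the preset correlation therefore passed lists readily, and its small adjusted p alone does not show that a list differs between lines. Of 100 drawn splits of the 9 arrays, 1, the real one, gave 5783 genes or more by the F test, the next giving 2808, and 1 gave 3232 or more genes changed the same way, the next giving 2581. A random assignment of these arrays to lines would thus rarely give such counts. If the arrays of a line were repeats of 1 culture, the splits could not tell line differences from chance differences between cultures. Such chance is therefore not excluded.

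Camera, which compares a list with the other genes, passed 10 lists for TR2 against TR1, and with an estimated correlation 1 of them, ATF4 targets, remained. The median log2 difference of TR2 minus TR1, not itself tested, was 0.46 for ATF4 targets, 0.25 for fatty acid synthesis, 0.25 for mitosis and G2/M, 0.18 for DNA replication and G1/S, 0.15 for histones and 0.093 for oestrogen receptor targets. It was -0.33 for immediate early genes, -0.14 for epithelial junctions, -0.12 for stem and progenitor genes and -0.079 for hypoxia and glycolysis. Genes higher in TR2 by limma's test of the difference were CA2 (5.31), CBLN2 (5.21), PGR (3.84), SCNN1A (3.04), CLIC3 (3.03), FGFBP2 (2.92) and ESR1 (0.6). Lower were CDKN2B (-3.35), SH3BGRL (-3.34), CLDN1 (-3.14), CSGALNACT1 (-3.12), GPNMB (-2.97), EGR3 (-2.91), TFF1 (-1.05), ERBB2 (-1.02), PDZK1 (-0.98), ABCG2 (-0.88), KRT8 (-0.87) and CDKN1A (-0.46). These are fitted differences. In TR1, CA2, CBLN2, PGR and CLIC3 lay under the background level, as CDKN2B, CLDN1, CSGALNACT1, EGR3 and ABCG2 did in TR2, so their values are no measure of size and give no order. Their bounds are at least 9.54-, 14.1-, 9.08- and 2.93-fold, and at least 2.56-, 7.68-, 3.85-, 4.02- and 1.23-fold. PDZK1 lay under it in both lines. Among 11721 probe sets without a gene name, which no comparison used, 439 changed in TR1, 512 in TR2 and 169 differed between TR2 and TR1.

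Interferon-response genes were lower in both resistant lines, with list medians of -0.92 in TR1 and -0.94 in TR2, which shrank to -0.41 and -0.46 with values raised to the background level, as 24 of the 42 genes averaged above it. Without parental replicate 1, which stood apart on the third component, the medians were -0.92 and -0.93, with the beta-actin end signal as a covariate -0.91 and -0.93, and with the hybridisation control level as a block -0.95 and -0.94. The first setting argues against parental replicate 1 as the whole cause. The block could not change the TR2 median, since parental and TR2 each held 1 array of high controls among 3. For TR1 its median of -0.95 argues against the control level as the whole cause. The beta-actin end signal was 1.52 to 2.49 in parental, 2.01 to 2.12 in TR1 and 1.33 to 2.43 in TR2 arrays. With such overlap the covariate had little room to move the medians, and no conclusion is drawn from it. TR2 and TR1 differed by a median of 0.074 in the list, and a raised interferon state of the parental cultures cannot be told apart from a fall in the resistant lines, since both comparisons use the same parental arrays. A lasting fall tied to resistance and an effect of the drug in the medium both stay open as hypotheses and were not tested.

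PGR fell less in TR2 than in TR1, while GREB1 and PDZK1 were low in both. Parental cells mixed into the TR2 cultures would bring PDZK1 and GREB1 along, but both lay under the background level in TR2, so their shares of the parental level (2.5% and 0.413% as measured) are at most 6.35% and 3.82%, against 69.9% for PGR, which argues against such mixing. The other PGR probe set differed by 1.72 between TR2 and TR1 in the same direction. Its values in both resistant lines lay under the background level, so a fault of the main probe set stays open. A difference between the lines in how PGR is controlled may remain as a hypothesis.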

How the results depend on the processing

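The hybridisation control block, the fit without both arrays of high controls, the beta-actin covariate and the raising of values to background were chosen after the data were seen. Under settings that change the threshold or the test, counts moved by construction. At adjusted p under 0.01, 3039 genes changed in TR1, 3128 in TR2, 942 differed between TR2 and TR1, 3805 differed among the lines, 2020 changed the same way in both, and 7 lists passed in TR2 against parental. Treat against a log2 change of 0.5 gave 1099, 1142 and 226 genes. With an estimated correlation 3, 2 and 1 lists passed, and fry passed 19 in TR1. In TR2 against parental 8 lists passed without the lowest 25% of genes and 7 without genes under the median of gene means, where fewer genes were tested. With values raised to the background level 3235 genes changed in TR1, 3311 changed in TR2 and 1215 differed between TR2 and TR1. Under that setting 3804 genes differed among the lines and 2251 changed the same way in both resistant lines. The correlation of fold changes across genes was 0.841 without genes under the median of gene means, 0.822 with the mean of probe sets, 0.823 with the hybridisation block and 0.822 with values raised to background; the cause was not tested. RPS9 in TR2 turned to -0.03 with the mean of its probe sets and to -0.53 with the most variable one, where it passed limma's test as lower (adjusted p = 0.033). TAP2 in TR2 turned to 0.04 with the most variable one. The first setting averages a gene's probe sets, and the second reads another one.

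Leaving out 1 array gave 3586 to 5164 genes in TR1, 3586 to 5179 in TR2, 4671 to 6140 among the lines, 2558 to 3517 changed the same way, a correlation of 0.822 to 0.84, and 9 to 12, 9 to 13 and 10 to 11 lists. Between TR2 and TR1 it gave 1074 (without TR2 replicate 2) to 2191 genes, and 1130 without TR1 replicate 3. The replicate numbers do not pair the arrays: 2 of 9 same-number pairs had deviations correlated over 0.1, from -0.48 to 0.21, and 0 of 9 arrays correlated best with their own number, while parental replicate 1 and TR1 replicate 2 correlated at 0.62. With the replicate number as a block, 4153, 4405 and 1384 genes and 10, 13 and 10 lists passed. Among the lines 4989 genes differed, and 2799 changed the same way. Each number holds 1 array of every line, so this block cannot change the fold changes, and their correlation stayed at 0.832 by construction.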

Other observations

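The tests of neighbouring genes were planned before their results were seen, and the genes and windows named singly here were chosen after. The 56 genes that changed in opposite directions in the resistant lines all differed between them by limma's direct test, which opposite calls against the same parental arrays all but fix in advance. Of these genes, 38 lay above the background level in all 3 lines. GPNMB, a transmembrane glycoprotein gene, rose by 2.19 in TR1 and fell by 0.78 in TR2, and the retinoic acid-induced gene GPRC5A rose by 1.84 and fell by 0.35. In the other direction, the serine synthesis gene PSAT1 fell by 0.96 in TR1 and rose by 0.53 in TR2, and the mitochondrial PEP carboxykinase gene PCK2 fell by 0.32 and rose by 0.66. PSAT1 and PCK2 belong to the ATF4 list. The luminal keratin gene KRT18 rose by 0.28 in TR1 and fell by 0.3 in TR2.

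Genes that neighbour each other in the order of assembly GRCh38.p14 shifted together. In TR2 against parental the most extreme window of 25 genes, from PHTF2 to PEG10, had a median of 0.754 against 0.56 for the 95th percentile of shuffled orders, which argues against a chance order of genes. With 1 gene kept per run of related symbols 46 windows in 5 blocks passed, against 45 in 7 with all genes, which argues against clusters of related genes as the whole cause in TR2, while the same step took TR1 from 30 windows in 5 blocks to 19 in 3, and TR2 against TR1 from 329 in 9 to 291 in 6. A gain or loss of chromosome segments may account for it and stays open. In that window 80% of the genes moved the same way, where over 80% had been required. In TR1 against parental 68% did in the most extreme window (PEX7 to SASH1, median 0.694). Over 80% did in 5 of the 7 blocks of TR2 and in 1 of 5 of TR1, all higher, on which the test had not been set. The 5 TR1 blocks were about as high in TR2, with medians of 0.35 to 0.54 in TR1 and 0.42 to 0.49 in TR2. Their medians of TR2 minus TR1 were -0.056 to 0.026. Both comparisons use the same parental arrays, so the counts of blocks in the 2 lines are not independent. In these blocks a shift in the parental line cannot be told apart from one in the resistant lines. In TR2 against TR1 the most extreme window ran from RAX to ATP9B with a median of 0.603 and 92% of genes moving the same way, a window that the test had not been set on. Nor had it been set on the 9 blocks of that comparison, where 71.1% to 93.3% of genes moved the same way. Windows and blocks were picked for a shifted median, which by itself makes most of their genes move the same way. Shares in shuffled orders were not computed, so the percentages do not tell whether a segment was gained or lost. The block from MRPL36 to DROSHA was lower in TR2 (median -0.29) and the others were higher. The longest, CIAO3 to GDPD3 with 205 genes, had 89.3% and medians against parental of -0.029 in TR1 and 0.29 in TR2. VDAC3 to LAPTM4B, with 105 genes, had 84.8% and medians of 0.098 and 0.42.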
